A study of Mus musculus with 6 samples.

How the data were processed

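RNA was measured in 6 libraries of mouse stromal-vascular cells, the cell fraction of fat tissue that holds the precursors of adipocytes. Per the labels' protocols, the cells came from the inguinal white fat of male mice 8 weeks old and were grown to confluence, which was called day 0. They then spent 2 days in an induction medium and the days up to day 6 in a maintenance medium. The induction medium held the phosphodiesterase inhibitor IBMX (0.5 mM), the glucocorticoid dexamethasone (5 µM), the cyclooxygenase inhibitor indomethacin (125 µM), insulin (850 nM), the thyroid hormone T3 (1 nM) and the PPAR gamma agonist rosiglitazone (1 µM). The maintenance medium kept insulin, T3 and rosiglitazone at the same doses. Polyadenylated RNA was captured on oligo-dT beads, broken into fragments of about 200 bp, reverse transcribed from random hexamers and amplified by PCR, per the labels' protocols. Reads without molecular identifiers are not independent molecules, so the intervals and floors given below cover counting error only.

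The deposited table holds 1 column of read counts per library. Per the submitters' processing notes, reads were aligned with TopHat2 2.0.13 and counted with HTSeq 0.9.1, and the builds named are mm10 and GRCm38. The counting settings, the gene annotation and the strand setting are not given in the sources used here. The column names say RPKM, but the deposited values are raw counts: they are whole numbers, each column ends in the 5 summary lines that HTSeq writes, and read as RPKM the column sums would need a mean gene length of only 33.9 to 44.4 bases. No normalization had been applied to them. The table has 45808 gene lines, all with a symbol. Of the symbols, 27 had been turned into calendar dates, of which 2 occurred more than once, and none of these is named here.

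Counts assigned to genes ranged from 22522221 to 29458374 per library. The 5 summary lines stayed out of library sizes and tests. HTSeq had set aside 2.62% to 3.23% of all counted alignments as outside any feature, 4.40% to 4.91% as ambiguous between genes and 4.16% to 9.05% as not uniquely aligned, and its other summary lines held 0. A count of 0 in a library allows a level of up to 3 counts, which was 0.0994 to 0.150 CPM in these libraries. A fold against a day with 0 counts in both libraries is given as a lower bound against this floor, taken per library. Where a day held 1 to 3 counts in all, the ratio of CPM is given with its exact 95% counting interval.

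Libraries were grouped by the day in their titles, 3 days with 2 libraries each. The series design calls the 2 libraries of a day biological replicates, and the titles number them 76 and 77. Whether they came from separate mice or cultures is not given in the sources used here, so the p-values measure the spread between these libraries, whatever its source. The counts of the 2 libraries of a day differed by more than sampling noise on every day (chi-square per degree of freedom 7.00 at day 0, 7.64 at day 2 and 26.7 at day 6), so each was counted once in n. As 2 preparations of 1 culture can also differ by more than counting noise, this does not show separate mice or cultures. Pearson's r of their log2 CPM across genes was 0.994, 0.993 and 0.989, over genes that are not independent replicates.

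The tests were fixed before the data were examined. Genes were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM scaling and edgeR's filter on low counts (filterByExpr), which kept 14459 genes and left 31349 untested. All 6 libraries entered a single fit with a mean per day, no further covariate and 3 residual degrees of freedom. Each of the 3 comparisons used the Benjamini-Hochberg adjustment over all genes tested with a threshold of 0.05, and a joint F test asked for a difference between any of the days. The common biological coefficient of variation was 0.0830. Fold changes and their standard errors come from this fit, and levels are CPM, counts scaled to a common library size, with TMM factors. The same steps were tested on simulated counts of 14150 genes, with 67, 67 and 66 changed by 1.5-, 2- and 4-fold. For day 2 against day 0, edgeR recovered 74.6%, 95.5% and 100% of them, and 3.23% of its calls were false. For day 6 against day 0 it recovered 65.7%, 88.1% and 98.5%, and 1.75% were false. In the data 67.1% and 70.9% of genes were called, so these rates may not hold there.

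The 76 and 77 labels were checked for pairing before the fits were compared, by the correlation across genes of same-numbered libraries' deviations from their day means (log2 CPM with a prior count of 2). Pearson's r was 0.109 between days 0 and 2, 0.112 between days 0 and 6 and 0.213 between days 2 and 6, with Spearman's rho 0.0589, 0.0546 and 0.176. All 3 passed the limit of 0.1 set beforehand, so the numbers were taken to pair the libraries. What they mark is not given in the sources used here. The main results carry no block, as fixed, and the fit with the replicate number as a block stands beside a result where it changed the call.

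In all, 36 gene lists were fixed before the data were examined, covering pathways, the targets of the medium components and markers of other cell types. Lists with fewer than 3 tested members (4 of them) were not tested. The other 32 were tested in each comparison with fry, which asks whether a list's genes move on balance in 1 direction, and with camera of limma 3.58.1, which compares a list with all other genes. Their p-values were adjusted over the lists within a comparison. Of 96 tests, fry called 78, camera with its preset correlation of 0.01 called 61, and camera with a correlation estimated from these libraries called 0, with a lowest adjusted p of 0.226. The estimate and its test rest on the 3 residual degrees of freedom, so this test has little power. Even general adipocyte genes at day 6 against day 0, 21 of 22 higher with a median of 170-fold, did not pass it. A list's failure to pass it therefore decides nothing, here and below. The count of members past the gene test is given over all genes tested, and also adjusted over the list alone where that count differs.

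The genes named follow a rule fixed before the data were examined. In every comparison, 10 genes are named whatever their result: Naa10, Ppargc1a, Ucp1, Cidea, Dio2, Prdm16, Pparg, Cebpa, Adipoq and Fabp4. To these come, per comparison, the 6 largest rises and the 6 largest falls among called genes with non-overlapping libraries and a mean of at least 10 CPM, leaving out symbols of predicted and RIKEN genes. From each list described in detail come the 2 called members with the largest change, the 2 with the highest mean level and, where called members went both ways, the largest change against the majority. Which lists are described in detail was chosen after their values were seen, and with them the names came to 40, 39 and 45 in the 3 comparisons, not counting Cidea, where the rule foresaw fewer. Some genes that this rule picked are not reported here. Gene positions, overlaps and shared sequence come from GENCODE M21 on GRCm38, in which 41919 of the deposited symbols were found. Shared sequence is the percent of the distinct 50-mers of a gene's transcripts that also occur in transcripts of genes at other loci, computed with Python 3.11.15. Figures were drawn with matplotlib 3.10.9.

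The alternatives fixed beforehand were median-of-ratios (RLE) scaling, library totals with no composition factor, no filter on low counts, DESeq2 1.42.0, limma-voom, the replicate number as a block, a direct test for changes beyond 2-fold, a threshold of 0.01, a fit of only the 2 days compared, and leaving out each library in turn. In the last, a day with 1 library left is assumed to vary like the others. That setting, the block and the 2-day fit leave fewer than 3 residual degrees of freedom, so a call lost there need not depend on the library named. Genes at day 2 and at day 6 were compared with the same day 0 libraries, so the overlap of their calls was set beside 20 simulations of unchanged groups and beside the overlap of independent lists.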

Results

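The series followed cultured mouse fat precursors on their way to beige adipocytes, fat cells that arise in white fat and can produce heat. Its title names Naa10, the catalytic subunit of an enzyme that acetylates the amino termini of proteins, as a brake on heat production by these cells that acts through PGC-1 alpha, the product of Ppargc1a. The 6 libraries analysed here are labelled WT, wild-type, and follow the course itself: confluent stromal-vascular cells at day 0, the same kind of culture after 2 days of induction medium, and at day 6 after the switch to maintenance medium. Each day had 2 libraries, numbered 76 and 77. In that order they held 29458374 and 23400500 counts in genes at day 0, 26292979 and 25057852 at day 2, and 26381822 and 22522221 at day 6. Levels below are mean CPM ± SD, with n = 2 libraries per day throughout, and folds come from the edgeR fit.

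The first principal component of log2 CPM held 61.2% of the variance and ordered the libraries by day, and the next held 34.0% and set day 2 apart from days 0 and 6. Of the 14459 genes tested, 12265 (84.8%) differed between at least 2 of the days by edgeR's quasi-likelihood test. The 10 most abundant genes of a library held 13.97% ± 0.893 of the counts at day 0, 6.80% ± 0.224 at day 2 and 12.6% ± 1.63 at day 6. Scd1, the desaturase that makes oleate from stearate, went from 0.0427% ± 0.00204 of the counts at day 0 to 0.534% ± 0.0174 at day 2 and 4.65% ± 0.868 at day 6. Genes of the mitochondrial genome went from 0.528% ± 0.0375 to 1.21% ± 0.114 and 3.51% ± 0.530. The share of alignments that HTSeq set aside as not unique moved with them, from 4.29% ± 0.186 to 6.43% ± 0.312 and 8.28% ± 1.10.

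The genes followed in every comparison lie at these places in GRCm38, with reads counted over exons. Naa10 lies on chromosome X from 73916873 to 73921944 on the minus strand, and 11.6% of its exonic length overlaps another gene. Ppargc1a lies on chromosome 5 from 51454250 to 51567726 (minus), Ucp1 on chromosome 8 from 83290352 to 83298452 (plus), Cidea on chromosome 18 from 67343604 to 67367785 (plus) and Dio2 on chromosome 12 from 90724552 to 90738438 (minus). Prdm16 lies on chromosome 4 from 154316125 to 154636873 (minus), Pparg on chromosome 6 from 115360951 to 115490399 (plus), Cebpa on chromosome 7 from 35119293 to 35121928 (plus), Adipoq on chromosome 16 from 23146536 to 23158028 (plus) and Fabp4 on chromosome 3 from 10204088 to 10208576 (minus).

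**Figure D1:**
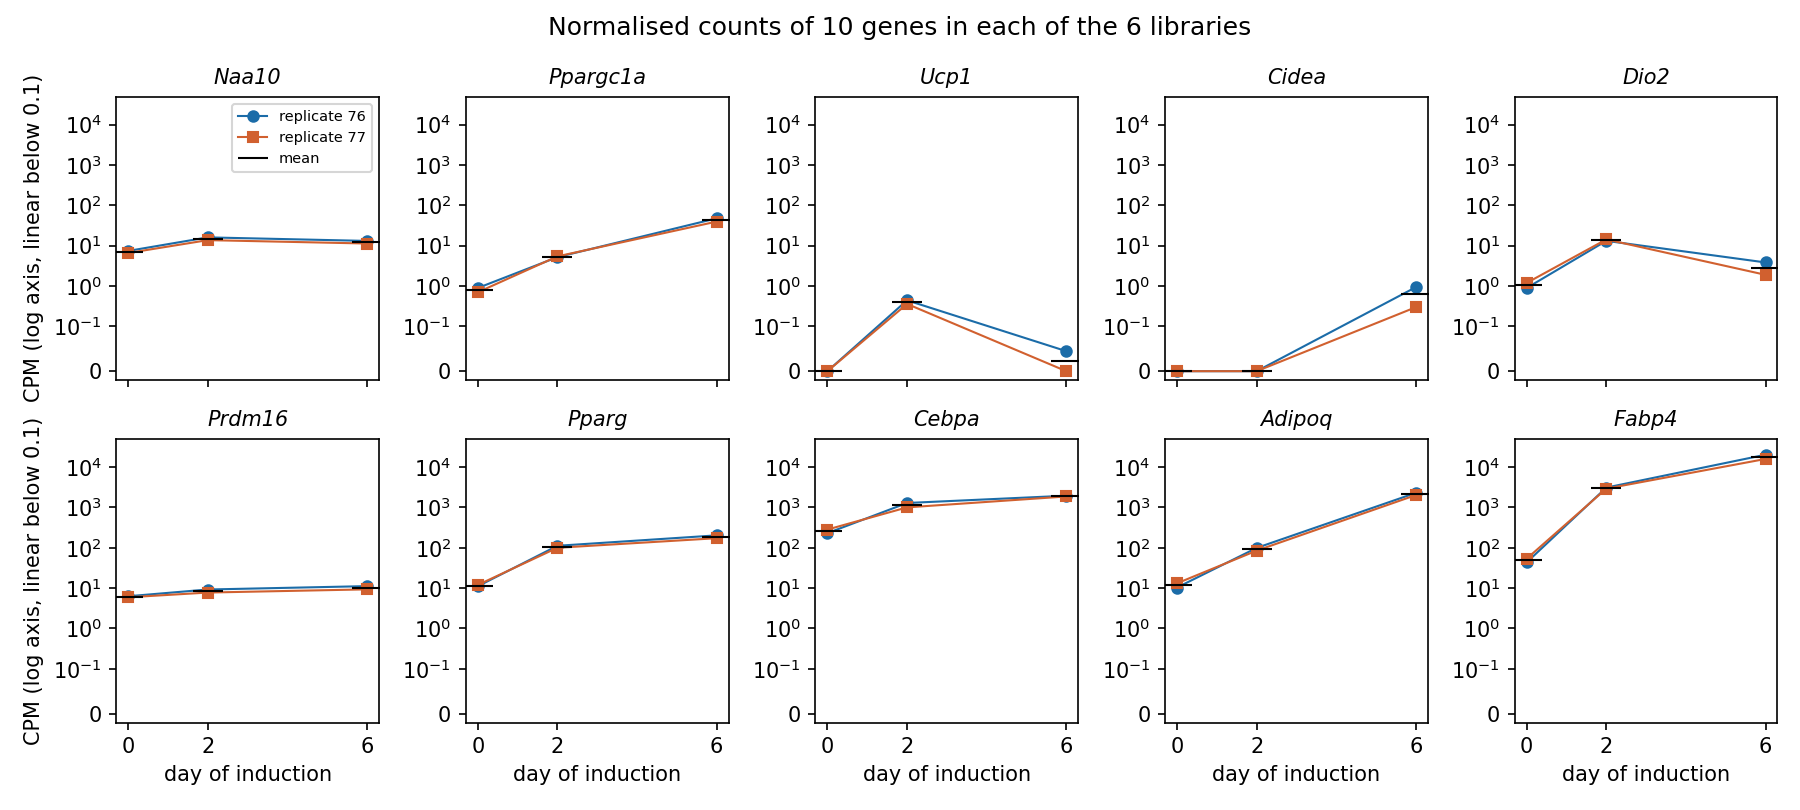
Level of the genes followed in every comparison in each library (CPM, log axis that is linear below 0.1) against the day of the course, with replicate 76 as circles, replicate 77 as squares and the mean of each day as a dash. Fabp4 climbed from 48.6 to 18135 CPM, while Ucp1 stood at 0 CPM at day 0, 0.401 at day 2 and 0.0223 at day 6.

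Day 2 was compared with day 0 to see what 2 days of induction medium changed. Adipocyte genes rose steeply: Fabp4, a fatty acid carrier, went from 48.6 ± 7.21 to 3020 ± 124 CPM (62.2-fold; log2 change 5.96, SE 0.20), and Adipoq, the hormone adiponectin, from 11.8 ± 1.99 to 92.2 ± 10.1 CPM (7.86-fold; SE 0.15). Pparg and Cebpa, the transcription factors that drive adipocyte formation, rose 9.20-fold (11.6 ± 0.608 to 106 ± 8.42 CPM) and 4.47-fold (257 ± 37.4 to 1148 ± 202 CPM). Naa10 rose 2.12-fold, from 7.005 ± 0.585 to 14.9 ± 1.65 CPM (log2 change 1.09, SE 0.14, adjusted p = 0.000175 by edgeR). Stress-fibre genes and interferon-stimulated genes fell, and genes of DNA replication and mitosis rose. With an estimated correlation camera called none of these lists, and the interferon call depended on the setting, as given below. In all, 9704 genes changed, 4853 higher and 4851 lower, and 1774 and 2586 of these had a fitted change of more than 2-fold. The median log2 change of all genes moved by 0.11 with library totals alone as the scaling and by 0.14 without replicate 77 of day 0.

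Among 20 tested genes of heat production in brown and beige adipocytes, 13 rose and 2 fell by day 2. Their median log2 change was 1.58, or 1.34 with genes at 0 placed at their bound (adjusted p = 0.00367 by edgeR's fry; adjusted p = 0.382 with an estimated correlation). Ppargc1a, the coactivator of mitochondrial and heat-producing genes, rose 6.56-fold, from 0.797 ± 0.137 to 5.32 ± 0.163 CPM. Dio2, which makes active thyroid hormone, rose 13.3-fold, from 1.04 ± 0.212 to 13.8 ± 0.795 CPM, and Letmd1, a mitochondrial protein, 1.98-fold to 39.5 ± 0.230 CPM. Ucp1, the uncoupling protein that turns the proton gradient into heat, had 0 counts in both day 0 libraries and 13 and 10 at day 2, at least 3.60-fold more than the floor of 3 counts per library (adjusted p = 0.00238 by edgeR). Elovl3, an elongase of very long fatty acids, went from 2 counts in all at day 0 to 612, a ratio of 291 with a counting interval of 80.3 to 2411. Prdm16, a regulator of brown fat identity, rose 1.39-fold, from 6.11 ± 0.255 to 8.51 ± 1.04 CPM (adjusted p = 0.0238 by edgeR). That call was lost without replicate 76 of day 0 (adjusted p = 0.0709 by edgeR) or of day 2 (adjusted p = 0.152), in a range of 0.00482 to 0.152 over all alternatives. Here and below, such ranges leave out the test for a change beyond 2-fold, which asks another question. Fabp3, a fatty acid carrier of muscle and brown fat, fell 15.2-fold to 0.105 ± 0.00418 CPM, although 29.2% of its 50-mers occur elsewhere. Cidea, a lipid droplet protein of brown fat, had 0 counts in all 4 libraries and was not tested.

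General adipocyte genes rose as well, and 20 of 22 were higher and 1 lower. Their median log2 change was 4.05, with adjusted p = 0.00119 by edgeR's fry and adjusted p = 0.299 with an estimated correlation. Cidec, a lipid droplet protein, rose 163-fold to 87.7 ± 6.86 CPM, the fatty acid transporter Cd36 65.6-fold from 6.51 ± 1.86 CPM, and Lpl, which frees fatty acids from lipoproteins, 6.56-fold to 5067 ± 175 CPM. The member that fell was Cfd, the adipokine adipsin, 2.32-fold lower at 10.3 ± 3.89 CPM (adjusted p = 0.00417 by edgeR). That call was lost without replicate 77 of day 0 (log2 change -0.71).

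All 18 contractile and myofibroblast genes fell. The list's median log2 change was -3.93, with adjusted p = 0.00119 by edgeR's fry and adjusted p = 0.299 with an estimated correlation. Smooth muscle actin, Acta2, fell 94.0-fold from 1433 ± 21.9 to 15.3 ± 2.39 CPM and the myosin light chain Myl9 99.8-fold from 227 ± 10.9 CPM. The abundant cytoskeletal genes Flna and Myh9 fell 3.06-fold and 4.17-fold, from 1786 ± 31.97 and 1373 ± 4.56 CPM. Markers of mural cells, the pericytes and smooth muscle cells of vessels, moved with them. Their summed level was 712 CPM at day 0 and 207 at day 2, and 6 of 9 fell (adjusted p = 0.00184 by edgeR's fry, adjusted p = 0.299 with an estimated correlation). Adjusted over the list alone, 1 mural marker also counted as higher. Of the markers of other cell types, Myh11 (mural) and Des (skeletal muscle) are also in the contractile list, and Pdgfrb (mural) and Eng (endothelial) in the progenitor list.

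Of 29 genes of S and G2/M phase, 28 rose and 1 fell. The median log2 change was 1.60, with adjusted p = 0.00190 by edgeR's fry and adjusted p = 0.299 with an estimated correlation. Rrm2, a subunit of ribonucleotide reductase, rose 5.93-fold to 291 ± 27.8 CPM and topoisomerase Top2a 3.53-fold to 257 ± 1.85 CPM. Ccnd1, the G1 cyclin D1, fell 10.7-fold to 5.94 ± 0.0392 CPM, with 23.4% of its exonic length overlapping another gene. Among 13 subunits of amino-terminal acetyltransferases, 9 rose and 2 fell (adjusted p = 0.00252 by edgeR's fry, adjusted p = 0.421 with an estimated correlation). The catalytic subunit Naa50 rose 2.45-fold to 321 ± 6.06 CPM, Naa15, the ribosome anchor that works with Naa10, 1.83-fold to 121 ± 0.142 CPM, and its relative Naa16 2.39-fold. Nat6 fell 1.40-fold to 8.28 ± 0.0652 CPM (adjusted p = 0.00402 by edgeR), a call lost without replicate 77 of day 0 (adjusted p = 0.0943 by edgeR, in a range of 0.00242 to 0.0943).

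Interferon response genes fell by day 2, 18 of 19 of them and with no member higher. Their median log2 change was -3.31, with adjusted p = 0.0141 by edgeR's fry and adjusted p = 0.421 with an estimated correlation. Ifit3 fell 36.8-fold from 33.4 ± 15.2 CPM, although 51.2% of its 50-mers occur elsewhere, and the transcription factor Stat2 3.51-fold from 100.4 ± 33.6 CPM. Mx2, which GENCODE M21 annotates as a polymorphic pseudogene, fell 33.2-fold from 2.43 ± 1.81 CPM (log2 change -5.06, or -3.95 without replicate 76 of day 0). The list's call was lost without replicate 76 of day 2 (adjusted p = 0.0867 by edgeR's fry), without replicate 77 of day 2 (adjusted p = 0.0670) and with the replicate number as a block (adjusted p = 0.0531), in a range of 0.0135 to 0.0867. Summed macrophage markers stood at 55.0 CPM at day 0 and 55.1 at day 2, and 1 of 13 was lower (adjusted p = 0.705 by edgeR's fry). The macrophage direction turned without replicate 77 of day 2 (adjusted p = 0.910 by edgeR's fry, in a range of 0.590 to 0.910).

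Beside that of Elovl3, the largest fitted rises were those of Acot5, a peroxisomal acyl-CoA thioesterase, Sptlc3, a subunit of the first enzyme of sphingolipid synthesis, the chemokine Cxcl13, the transcription factor Zbtb16 and the microtubule protein Map7d2. Acot5 and Sptlc3 had 0 counts at day 0 and rose at least 178-fold and at least 52.9-fold, to 19.9 ± 1.53 and 5.90 ± 2.14 CPM, and 22.1% of the 50-mers of Acot5 occur elsewhere. Fitted folds over 0 counts depend on the prior, so the bounds do not support the rank of these 2 genes. Cxcl13 rose 332-fold to 86.9 ± 12.5 CPM, Zbtb16 250.5-fold to 79.4 ± 0.0979 CPM and Map7d2 195-fold to 54.6 ± 5.12 CPM. The largest falls were those of Nov, a matricellular protein (355-fold, from 349 ± 12.3 CPM), the cadherin Cdh3 (165-fold, from 41.0 ± 6.65 CPM), the collagen Col8a1 (153-fold, from 252 ± 16.6 CPM), the matricellular protein Ctgf (from 221 ± 1.28 to 2.1997 ± 0.755 CPM), Myl9 and the sorting receptor Sorcs2 (97.6-fold, from 68.7 ± 11.6 CPM). The log2 change of Cdh3 of -7.36 became -8.17 without replicate 77 of day 2. The highest adjusted p of these genes was 3.82e-05 by edgeR.

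Among the other lists, those of lipid handling and of PPAR, glucocorticoid and cyclic AMP targets rose by day 2. Of 22 lipogenesis genes 18 were higher and 3 lower (4 lower adjusted over the list alone), all 14 lipolysis and lipid droplet genes were higher, and 17 of 20 PPAR targets were higher and 1 lower. Further, 16 of 24 adipogenic transcription factors were higher and 4 lower, 14 of 19 glucocorticoid targets were higher and 3 lower, and 13 of 18 cyclic AMP targets were higher and 3 lower. Their adjusted p ranged from 0.000825 to 0.00158 by edgeR's fry, and each had adjusted p = 0.299 with an estimated correlation. Beige-selective markers split into 6 higher and 6 lower of 12 (adjusted p = 0.000825 by edgeR's fry, adjusted p = 0.377 with an estimated correlation), with a median log2 change of 0.09. Thyroid hormone targets had 7 higher and 3 lower of 11 (adjusted p = 0.0255 by edgeR's fry, adjusted p = 0.608 with an estimated correlation). That call was lost without replicate 76 of day 0 (adjusted p = 0.161 by edgeR's fry) or of day 2 (adjusted p = 0.0921), without replicate 77 of day 0 (adjusted p = 0.101) or of day 2 (adjusted p = 0.0955). It was also lost with the replicate number as a block (adjusted p = 0.0593 by edgeR's fry), in a range of 0.00290 to 0.161. Mitochondrial lists rose too, with 73 of 80 nuclear respiratory genes higher (74 adjusted over the list alone), and 10 of 12 respiratory genes of the mitochondrial genome. Of the others, 19 of 19 citrate cycle genes were higher, 23 of 27 fatty acid oxidation genes with 2 lower, and 13 of 20 biogenesis regulators with 1 lower. Their adjusted p ranged from 0.00119 to 0.00964 by edgeR's fry and from 0.319 to 0.423 with an estimated correlation. The nuclear respiratory call was lost without replicate 76 of day 0 (adjusted p = 0.0589 by edgeR's fry) or of day 2 (adjusted p = 0.0515), in a range of 0.00408 to 0.0589. The mitochondrial-genome call was lost without replicate 76 of day 0 (adjusted p = 0.0622 by edgeR's fry) or replicate 77 of day 2 (adjusted p = 0.0561), in a range of 0.00576 to 0.0622.

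Lists of the precursor state fell by day 2. Progenitor markers had 17 of 20 lower and 1 higher, anti-adipogenic regulators 18 of 22 lower and 1 higher, and matrix genes 20 of 27 lower and 1 higher. Adjusted p for these lay from 0.00407 to 0.0110 by edgeR's fry and from 0.370 to 0.421 with an estimated correlation. The progenitor call was lost without replicate 76 of day 0 (adjusted p = 0.0589 by edgeR's fry) or of day 2 (adjusted p = 0.0721) and without replicate 77 of day 0 (adjusted p = 0.0705) or of day 2 (adjusted p = 0.0561). Its lowest value over the alternatives was 0.00704. Prostaglandin pathway genes had 9 of 14 lower and 4 higher (adjusted p = 0.0141 by edgeR's fry, adjusted p = 0.423 with an estimated correlation). Their call was lost without replicate 76 of day 0 (adjusted p = 0.0589 by edgeR's fry) or of day 2 (adjusted p = 0.0935), without replicate 77 of day 0 (adjusted p = 0.105) or of day 2 (adjusted p = 0.0670). Library totals ended it as well (adjusted p = 0.0910 by edgeR's fry), and the lowest value was 0.0101. Unfolded protein and stress genes had 8 of 19 lower and 5 higher, and genes of UCP1-independent heat production 3 of 7 lower, with adjusted p of 0.00528 and 0.00190 by edgeR's fry and of 0.423 and 0.370 with an estimated correlation. Markers of other cell types moved beside them. Endothelial markers had 8 of 10 lower and 1 higher (summed level 121 to 38.9 CPM) and Schwann cell markers 4 of 6 lower (396 to 193 CPM). Their adjusted p was 0.00252 and 0.000595 by edgeR's fry and 0.370 and 0.299 with an estimated correlation. Skeletal muscle markers had 3 of 5 lower (36.3 to 8.52 CPM; adjusted p = 0.0631 by edgeR's fry), and passed without replicate 76 of day 2 (adjusted p = 0.0352 by edgeR's fry, in a range of 0.0352 to 0.376). Glycolysis genes, 5 higher and 4 lower of 19 (4 higher adjusted over the list alone), and cytokine and chemokine genes, 4 higher and 7 lower of 15, did not pass (adjusted p = 0.705 and 0.617 by edgeR's fry). The glycolysis median of 0.19 differed in sign from the mean of -0.01. The cytokine and chemokine direction turned with library totals (adjusted p = 0.894 by edgeR's fry) and without replicate 76 of day 2 (adjusted p = 0.716), in a range of 0.0810 to 0.894.

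**Figure D2:**
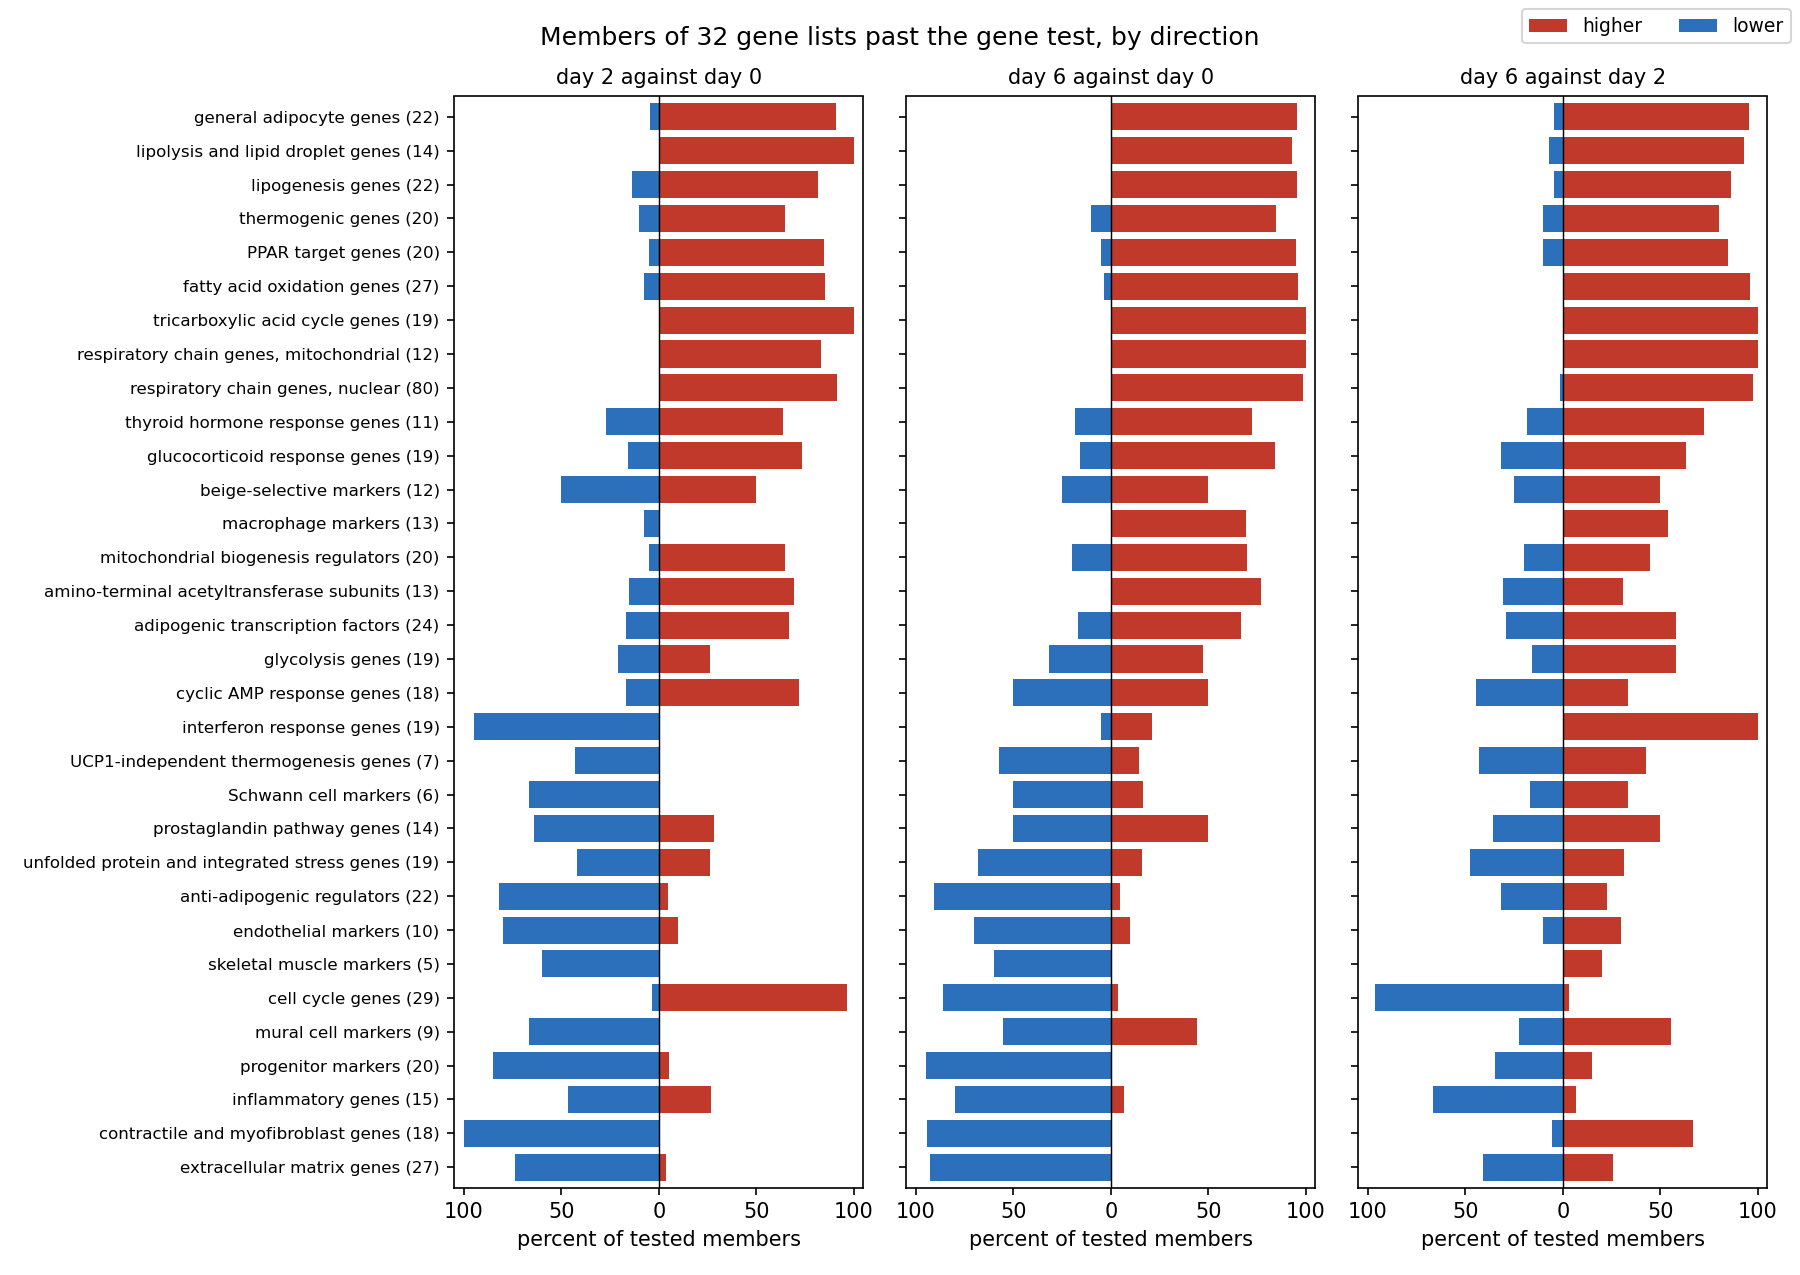
Percent of each list's tested members that passed the gene test as higher (red) or lower (blue) in each comparison, with the number tested in brackets, ordered by the list's median change at day 6 against day 0. Cell cycle genes turned from 28 higher of 29 at day 2 against day 0 to 28 lower of 29 at day 6 against day 2. With library totals as the scaling, the fry direction turned for cytokine and chemokine genes at day 2 against day 0, and for matrix, UCP1-independent, acetyltransferase, prostaglandin and skeletal muscle lists at day 6 against day 2.

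Day 6 was compared with day 0 to see what the whole course changed. Adipocyte genes reached their highest levels of the 3 days: Fabp4 stood at 18135 ± 3090 CPM (374-fold higher than at day 0), Adipoq at 2167 ± 192 CPM (185-fold), Pparg at 188 ± 21.5 CPM (16.3-fold) and Cebpa at 1915 ± 58.1 CPM (7.45-fold). Ppargc1a reached 43.7 ± 5.74 CPM, 53.9-fold higher (log2 change 5.75, SE 0.17), while Ucp1 stayed near 0, with 1 and 0 counts. Naa10 was 1.74-fold higher at 12.2 ± 1.28 CPM (log2 change 0.80, SE 0.14, adjusted p = 0.00105 by edgeR). Genes of lipid synthesis and of the respiratory chain rose, and most genes of the matrix list fell. With an estimated correlation camera called none of these lists. In all, 10253 genes changed, 5184 higher and 5069 lower, and 2678 and 2663 of these had a fitted change of more than 2-fold. With library totals alone as the scaling, 38.0% of the calls were higher instead of 50.6%, and the median log2 change of all genes moved by -0.25.

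Of the 20 thermogenic genes, 17 were higher and 2 lower at day 6 (median log2 change 4.55, or 3.81 with genes at 0 at their bound, adjusted p = 0.000731 by edgeR's fry, adjusted p = 0.226 with an estimated correlation). Ucp1 was not called (adjusted p = 0.269 by edgeR) and both days lay at or under the floor of 3 counts. Cidea, below the filter and not tested, had 21 and 6 counts at day 6 and 0 at day 0, at least 5.55-fold more than the floor. Dio2 was 2.80-fold higher at 2.87 ± 1.38 CPM (log2 change 1.49, or 0.88 without replicate 76 of day 6) and Prdm16 1.68-fold at 10.3 ± 1.33 CPM. Elovl3 went from 2 counts to 459 ± 16.9 CPM, a ratio of 12476 with a counting interval of 3453 to 103021, and Plin5, a lipid droplet protein that contacts mitochondria, from 1 count to 48.1 ± 9.33 CPM, a ratio of 2639 (473 to 104295). Letmd1 was 6.34-fold higher at 126 ± 8.91 CPM. Acot11, an acyl-CoA thioesterase, was 3.49-fold lower at 3.55 ± 0.909 CPM, with 20.9% of its exonic length overlapping another gene.

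Lipogenesis genes rose as a list, with 21 of 22 higher. The list's median log2 change was 5.09, with adjusted p = 0.000484 by edgeR's fry and adjusted p = 0.226 with an estimated correlation. Scd1 went from 414 ± 16.2 to 53688 ± 11816 CPM (130-fold), fatty acid synthase Fasn from 318 ± 25.7 to 13586 ± 1243 CPM (42.7-fold). Thrsp, a regulator of fatty acid synthesis, went from 0.351 ± 0.0280 to 2166 ± 840.2 CPM (6122-fold), and Agpat9, an enzyme of triglyceride synthesis, from 0.570 ± 0.224 to 160.5 ± 1.21 CPM. Nuclear genes of the respiratory chain had 79 of 80 higher. The median log2 change was 2.47, with adjusted p = 0.00128 by edgeR's fry and adjusted p = 0.275 with an estimated correlation. The ATP synthase subunits Atp5b and Atp5a1 rose 8.09-fold to 5544 ± 660.3 CPM and 5.60-fold to 2568 ± 309.5 CPM. Cox7a1, a subunit of cytochrome oxidase in muscle and brown fat, rose 52.7-fold to 80.8 ± 23.6 CPM, and Cox8b went from 1 count to 8.71 ± 6.25 CPM, a ratio of 488 (87.0 to 19317).

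Beige-selective markers, a list meant to tell beige from classical brown adipocytes, had 6 of 12 higher and 3 lower. Their median log2 change was 1.61, with adjusted p = 0.000481 by edgeR's fry and adjusted p = 0.226 with an estimated correlation. The potassium channel Kcnk3, which the thermogenic list also holds, rose 500.5-fold to 113 ± 12.96 CPM, the amino acid transporter Slc36a2 108-fold to 448 ± 68.3 CPM and Mtus1 19.6-fold to 256.3 ± 12.9 CPM. Tmem26, a surface marker of beige cells, was 12.9-fold lower at 0.311 ± 0.124 CPM.

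Matrix genes were lower at day 6, 25 of 27 with no member higher. The list's median log2 change was -2.36, with adjusted p = 0.00203 by edgeR's fry and adjusted p = 0.346 with an estimated correlation. The fibrillar collagens Col1a1 and Col3a1 fell 8.92-fold, from 28438 ± 3265 to 3188 ± 1032 CPM, and 9.12-fold, from 24803 ± 2107 to 2720 ± 777 CPM. Col8a1 and the proteoglycan Lum fell 12.9-fold and 9.22-fold. Markers of endothelial cells moved with them, with 7 of 10 lower and 1 higher and a summed level of 60.4 CPM (adjusted p = 0.0143 by edgeR's fry, adjusted p = 0.528 with an estimated correlation). That call was lost without replicate 76 of day 6. Schwann cell markers had 3 of 6 lower and 1 higher and a summed level of 232 CPM (adjusted p = 0.00411 by edgeR's fry, adjusted p = 0.640 with an estimated correlation). Their call was lost without replicate 76 or 77 of day 0, and without replicate 76 or 77 of day 2, a day not compared here.

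The largest fitted rises at day 6 by the naming rule were those of Plbd1, a phospholipase B homologue (at least 624-fold, to 69.5 ± 4.76 CPM), Sptlc3 (at least 552-fold, to 61.6 ± 8.35 CPM), Elovl3, Cidec (9816-fold, to 5278 ± 432 CPM), Thrsp and the aldehyde dehydrogenase Aldh3b2. Plbd1 and Sptlc3 had 0 counts at day 0, and their bounds do not support their rank. Aldh3b2 went from 2 counts to 181 ± 35.3 CPM, a ratio of 4959 (1372 to 40954), with 24.2% of its 50-mers occurring elsewhere. The largest falls were those of Tnmd, or tenomodulin (71.6-fold, from 37.3 ± 17.0 CPM), the chemokines Cxcl14 (44.2-fold, from 805 ± 49.5 CPM) and Cxcl5 (40.8-fold, from 102 ± 17.3 CPM). They were followed by those of the matrix protein Tgfbi (32.2-fold, from 70.01 ± 15.6 CPM), Aldh1a2, which makes retinoic acid (24.4-fold, from 70.001 ± 5.96 CPM), and Nov (23.5-fold). Without replicate 77 of day 6 the log2 changes of Cxcl14, Cxcl5 and Aldh1a2 went from -5.47, -5.35 and -4.61 to -6.22, -6.19 and -5.43. The highest adjusted p of these genes was 6.12e-06 by edgeR.

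Of the remaining lists at day 6 against day 0, general adipocyte genes had 21 of 22 higher, lipolysis and lipid droplet genes 13 of 14, and fatty acid oxidation genes 26 of 27 with 1 lower. The citrate cycle list had 19 of 19 higher, PPAR targets 19 of 20 with 1 lower and adipogenic transcription factors 16 of 24 with 4 lower. Their adjusted p ranged from 0.000481 to 0.000743 by edgeR's fry, and each had adjusted p = 0.226 with an estimated correlation. Respiratory genes of the mitochondrial genome had 12 of 12 higher, biogenesis regulators 14 of 20 with 4 lower and glucocorticoid targets 16 of 19 with 3 lower, with adjusted p from 0.000636 to 0.00203 by edgeR's fry and adjusted p = 0.275 with an estimated correlation. Of the 13 protein genes of the mitochondrial genome, 5 have over 90% of their 50-mers elsewhere, so their counts are uncertain. Acetyltransferase subunits had 10 of 13 higher and thyroid hormone targets 8 of 11 higher with 2 lower, both with adjusted p = 0.00203 by edgeR's fry, and adjusted p = 0.528 and 0.346 with an estimated correlation. The thyroid list's median log2 change was 2.45, or 1.49 with genes at 0 at their bound. Cyclic AMP targets split into 9 higher and 9 lower of 18 (adjusted p = 0.00747 upward by edgeR's fry, adjusted p = 0.667 with an estimated correlation). The call was lost without replicate 76 of day 0 (adjusted p = 0.0565 by edgeR's fry) or replicate 77 of day 0 (adjusted p = 0.0697), in a range of 0.00778 to 0.0697. Mural markers had 4 higher and 5 lower of 9 with a summed level of 732 CPM, and fry called them upward (adjusted p = 0.00647 by edgeR's fry, adjusted p = 0.779 with an estimated correlation) while their median and mean log2 changes were -1.73 and -0.34.

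Contractile genes were lower at day 6, 17 of 18 (18 adjusted over the list alone), progenitor markers 19 of 20, anti-adipogenic regulators 20 of 22 with 1 higher, and cell cycle genes 25 of 29 with 1 higher. Cytokine and chemokine genes were lower in 12 of 15 cases with 1 higher, unfolded protein and stress genes 13 of 19 with 3 higher, and UCP1-independent genes 4 of 7 with 1 higher. Their adjusted p ranged from 0.00108 to 0.00455 by edgeR's fry and from 0.275 to 0.392 with an estimated correlation. Macrophage markers had 9 of 13 higher with a summed level of 121 CPM, but the list did not pass (adjusted p = 0.249 by edgeR's fry). Glycolysis genes (9 higher and 6 lower of 19), prostaglandin pathway genes (7 and 7 of 14), interferon response genes (4 and 1 of 19, or 2 and 1 adjusted over the list alone) and skeletal muscle markers (0 and 3 of 5) did not pass either, with adjusted p from 0.0974 to 0.565 by edgeR's fry. The interferon median of -0.11 was opposite in sign to the mean of 0.17, and the fry direction turned without replicate 77 of day 0 (adjusted p = 0.942) or of day 6 (adjusted p = 0.979), in a range of 0.310 to 0.979. Glycolysis passed without replicate 77 of day 6 (adjusted p = 0.0336 by edgeR's fry, in a range of 0.0336 to 0.380). Prostaglandin genes passed downward with RLE scaling (adjusted p = 0.0413 by edgeR's fry) and library totals (adjusted p = 0.0262), and turned to higher without replicate 76 of day 6 (adjusted p = 0.920), in a range of 0.0262 to 0.920. Muscle markers passed without replicate 76 of day 2 (adjusted p = 0.0272 by edgeR's fry) and with only the 2 days compared (adjusted p = 0.0274, in a range of 0.0272 to 0.522).

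**Figure D3:**
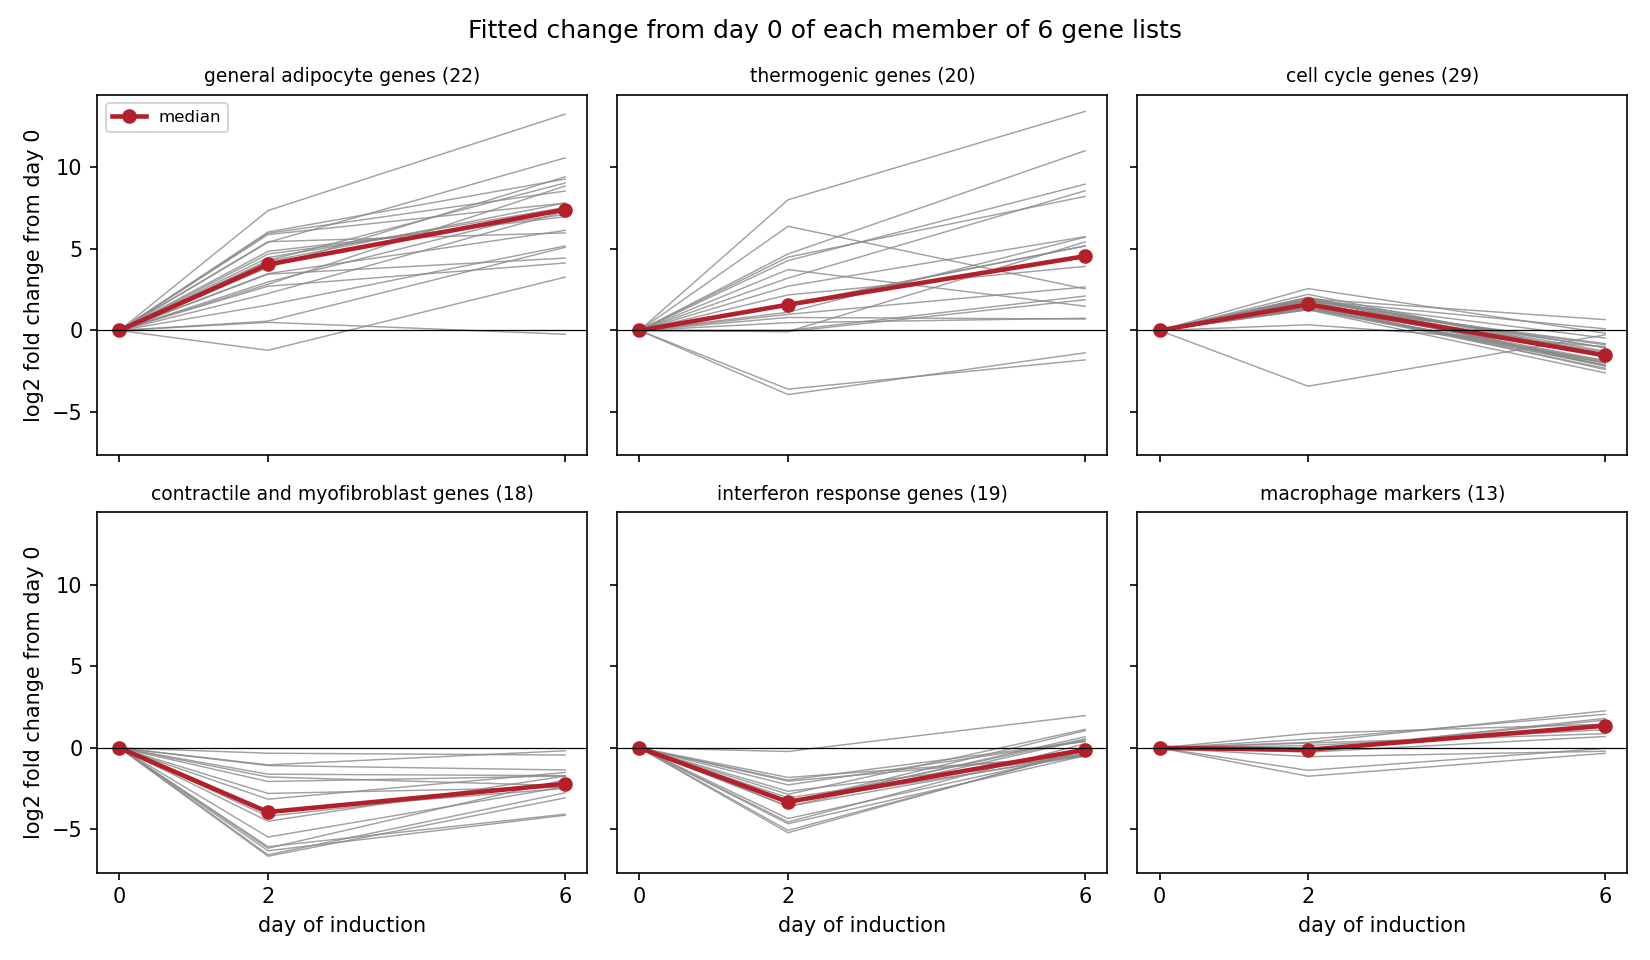
Fitted log2 change from day 0 at days 2 and 6 for each member (grey) and for the median (red) of 6 gene lists. Interferon response genes fell to a median of -3.31 at day 2 and lay at -0.11 at day 6, and fitted values of genes with counts at or near 0 depend on the prior and are no bound.

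Day 6 was compared with day 2 to see what followed the switch to maintenance medium. Ppargc1a rose a further 8.21-fold (log2 change 3.04, SE 0.13), Adipoq 23.5-fold (4.55, SE 0.15), Fabp4 6.00-fold, Pparg 1.77-fold and Cebpa 1.67-fold, while Dio2 fell 4.74-fold (log2 change -2.24, or -2.86 without replicate 76 of day 6) and Ucp1 fell from 23 counts in all to 1. Naa10 stood at 14.9 ± 1.65 CPM at day 2 and 12.2 ± 1.28 at day 6 and was not called (log2 change -0.28, SE 0.13, adjusted p = 0.0922 by edgeR). Replication and mitosis genes fell, interferon response genes rose, and contractile genes rose in part. With an estimated correlation camera called none of these lists, and the last 2 fry calls depended on the setting, as given below. In all, 9501 genes changed, 5520 higher and 3981 lower, and 2774 and 1505 of these had a fitted change of more than 2-fold. With library totals as the scaling, 37.1% of the calls were higher instead of 58.1%, and the median log2 change of all genes moved by -0.36. It moved by -0.13 without replicate 77 of day 0 and by -0.14 with only the 2 days compared.

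Among those genes, the Naa10 value passed as lower with RLE scaling (adjusted p = 0.0471 by edgeR), library totals (adjusted p = 0.00247) and only the 2 days compared (adjusted p = 0.0367). It also passed without replicate 76 of day 6 (adjusted p = 0.0475 by edgeR) and without replicate 77 of day 0 (adjusted p = 0.0358), in a range of 0.00247 to 0.413. Ucp1 had a ratio of 17.1 lower with a counting interval of 2.77 to 703 (adjusted p = 0.00818 by edgeR). Its call was lost with DESeq2 (adjusted p = 0.0544) and without replicate 77 of day 6 (adjusted p = 0.0510 by edgeR), in a range of 0.00256 to 0.0544. The Cebpa call (adjusted p = 0.00212 by edgeR) was lost with library totals (adjusted p = 0.0548, in a range of 5.82e-14 to 0.0548). Prdm16 stood at 8.51 ± 1.04 and 10.3 ± 1.33 CPM and was not called (adjusted p = 0.143 by edgeR), and its log2 change of 0.27 turned to -0.089 with library totals (adjusted p = 0.610, in a range of 0.0566 to 0.610).

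Thermogenic genes rose further, 16 of 20 higher and 2 lower. The median log2 change was 2.80, with adjusted p = 0.00102 by edgeR's fry and adjusted p = 0.257 with an estimated correlation. Plin5 rose 80.3-fold to 48.1 ± 9.33 CPM and Cpt1b, the muscle and brown fat carnitine transferase of fatty acid import, 45.0-fold to 4.93 ± 0.983 CPM, although 81.4% of its exonic length overlaps another gene. Cpt1b had 1 and 5 counts at day 2, and its log2 change of 5.49 became 4.74 without replicate 76 and 6.98 without replicate 77 of day 2. Elovl3 rose 42.8-fold and Letmd1 3.20-fold. Cidea, not tested, went from 0 counts to 21 and 6, at least 5.90-fold more than the floor. All 19 citrate cycle genes rose. Their median log2 change was 2.01, with adjusted p = 0.00178 by edgeR's fry and adjusted p = 0.342 with an estimated correlation. Mpc1, the mitochondrial pyruvate carrier, rose 8.66-fold to 54.5 ± 9.36 CPM, with 23.1% of its exonic length overlapping another gene. Pyruvate dehydrogenase Pdhb rose 8.04-fold to 1377 ± 243 CPM and pyruvate carboxylase Pcx 7.67-fold to 4532 ± 784.6 CPM.

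Cell cycle genes fell, 28 of 29 with 1 higher. The list's median log2 change was -3.27, with adjusted p = 0.00102 by edgeR's fry and adjusted p = 0.257 with an estimated correlation. The mitotic genes Bub1 and Kif11 fell 18.4-fold and 15.9-fold, to 2.04 ± 0.141 and 3.67 ± 0.519 CPM, Top2a 15.4-fold and Rrm2 6.67-fold. Ccnd1 rose 8.87-fold to 52.8 ± 13.7 CPM, with the overlap given above.

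Interferon response genes rose, all 19 of them. The median log2 change was 3.86, with adjusted p = 0.0127 by edgeR's fry and adjusted p = 0.615 with an estimated correlation. Ifit3 rose 34.0-fold to 31.2 ± 11.1 CPM, with the shared sequence given above, Mx2 29.3-fold to 2.198 ± 0.771 CPM, and Stat2 2.50-fold to 71.7 ± 20.3 CPM. The list's call was lost without replicate 76 of day 2 (adjusted p = 0.0880 by edgeR's fry), replicate 77 of day 2 (adjusted p = 0.0670) or replicate 77 of day 6 (adjusted p = 0.0508). It was also lost with the replicate number as a block (adjusted p = 0.0539 by edgeR's fry), in a range of 0.0123 to 0.0880. Macrophage markers moved beside them, 7 of 13 higher, with a summed level of 55.1 CPM at day 2 and 121 at day 6, but did not pass as a list (adjusted p = 0.202 by edgeR's fry). They passed without replicate 77 of day 6 (adjusted p = 0.0410 by edgeR's fry, in a range of 0.0410 to 0.485).

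Contractile genes rose in part, 12 of 18 higher and 1 lower (13 and 2 adjusted over the list alone), with a median log2 change of 1.69 (adjusted p = 0.00932 by edgeR's fry, adjusted p = 0.615 with an estimated correlation). The list's call was lost without replicate 76 of day 2 (adjusted p = 0.0628 by edgeR's fry), without replicate 77 of day 2 (adjusted p = 0.0615) and with only the 2 days compared (adjusted p = 0.0515), in a range of 0.00310 to 0.0628. Lmod1, which nucleates actin in smooth muscle, rose 18.4-fold to 12.6 ± 1.61 CPM and Acta2 13.97-fold to 213 ± 80.3 CPM. Flna stood at 584 ± 37.0 and 549 ± 113 CPM (adjusted p = 0.591 by edgeR). It passed as lower with library totals (adjusted p = 0.0341 by edgeR) and without replicate 77 of day 6 (adjusted p = 0.0102). Its log2 change turned to 0.11 without replicate 76 of day 6 (adjusted p = 0.323 by edgeR), in a range of 0.0102 to 0.898. Myh9 stood at 329 ± 32.6 and 416 ± 99.2 CPM (adjusted p = 0.0831 by edgeR). It passed as higher with no filter (adjusted p = 0.00136 by edgeR), with the replicate number as a block (adjusted p = 0.0398) and without replicate 76 of day 6 (adjusted p = 0.000459, the lowest over the alternatives). The log2 change of Myh9 turned to -0.013 with library totals (adjusted p = 0.952 by edgeR, the highest over the alternatives). Smtn, a stress-fibre protein, fell 1.44-fold to 7.31 ± 2.50 CPM (adjusted p = 0.0379 by edgeR). That call was lost without replicate 76 of day 0 (a day not compared here), day 2 or day 6, or replicate 77 of day 2. Mural markers moved with the list, with 5 of 9 higher and 2 lower and a summed level that went from 207 to 732 CPM (adjusted p = 0.00102 by edgeR's fry, adjusted p = 0.257 with an estimated correlation).

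Cyclic AMP targets split, 6 higher and 8 lower of 18, and fry called them downward. Their median log2 change was -0.21, with adjusted p = 0.0167 by edgeR's fry and adjusted p = 0.615 with an estimated correlation. The call was lost without replicate 76 of day 0 (adjusted p = 0.0608 by edgeR's fry), replicate 77 of day 2 (adjusted p = 0.0533) or replicate 77 of day 6 (adjusted p = 0.0751). It was also lost with the replicate number as a block (adjusted p = 0.0553 by edgeR's fry), in a range of 0.00293 to 0.0751. The nuclear receptor Nr4a1 fell 12.4-fold to 7.76 ± 1.37 CPM. Pck1, the enzyme of glycerol and glucose synthesis, rose 62.9-fold to 6.87 ± 1.53 CPM, and the phosphodiesterase Pde3b 2.33-fold to 762 ± 118 CPM. Pck1 had 6 and 0 counts at day 2, so its fold rests on 1 library. Its log2 change of 5.97 became 5.03 without replicate 77 of day 2, and without replicate 76 no count was left at day 2. The clock gene Per1 rose 1.24-fold to 90.03 ± 7.13 CPM (adjusted p = 0.0108 by edgeR). Its call was lost with DESeq2 (adjusted p = 0.0663), only the 2 days compared (adjusted p = 0.116 by edgeR), without replicate 76 of day 2 (adjusted p = 0.0867 by edgeR) and without replicate 77 of day 0 (adjusted p = 0.132). The log2 change of Per1 turned to -0.051 with library totals (adjusted p = 0.569 by edgeR, in a range of 0.00197 to 0.569).

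The largest fitted rises from day 2 by the naming rule were those of the adenosine receptor Adora1 (496-fold, to 115 ± 19.7 CPM, with 20.1% of its exonic length overlapping another gene), Tmem182 (433-fold, to 77.7 ± 10.2 CPM), and Thrsp (226-fold). Next came the cytochrome Cyp2e1 (194-fold, to 221 ± 64.0 CPM), the acute-phase protein Orm1 (193-fold, to 34.6 ± 6.31 CPM, with 20.4% of its 50-mers elsewhere) and Aldh3b2 (171.5-fold, with the shared sequence given above). The largest falls were those of Cxcl13 (61.1-fold, to 1.43 ± 0.511 CPM), the angiotensin receptor Agtr2 (29.7-fold, to 1.05 ± 0.281 CPM), and Prl2c2, a prolactin relative (27.3-fold, with 83.3% of its 50-mers elsewhere). Next came the acute-phase protein Saa3 (24.2-fold, to 2.22 ± 0.0390 CPM), the cytokine Il33 (22.4-fold, to 2.24 ± 1.84 CPM) and the phosphatase Alpl (21.7-fold, to 3.58 ± 1.08 CPM). Tmem182 had 9 and 1 counts at day 2, and its log2 change of 8.76 became 10.89 without replicate 76 and 7.96 without replicate 77 of day 2. That of Il33 of -4.49 became -3.79 without replicate 76 and -5.70 without replicate 77 of day 6. The highest adjusted p of these genes was 4.45e-05 by edgeR.

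Of the remaining lists at day 6 against day 2, general adipocyte genes had 21 of 22 higher and 1 lower, lipogenesis genes 19 of 22 and 1 lower, and lipolysis and lipid droplet genes 13 of 14 and 1 lower. Fatty acid oxidation genes had 26 of 27 higher, PPAR targets 17 of 20 and 2 lower, and beige-selective markers 6 of 12 and 3 lower. Their adjusted p ranged from 0.00102 to 0.00124 by edgeR's fry, and each had adjusted p = 0.257 with an estimated correlation. Nuclear respiratory genes had 78 of 80 higher and 1 lower, those of the mitochondrial genome 12 of 12 higher, and thyroid hormone targets 8 of 11 higher and 2 lower. Adjusted p for these ranged from 0.00304 to 0.00662 by edgeR's fry and from 0.448 to 0.482 with an estimated correlation. The mitochondrial-genome call was lost without replicate 76 or replicate 77 of day 2 (adjusted p = 0.0533 each by edgeR's fry, in a range of 0.00496 to 0.0533). Adipogenic transcription factors had 14 of 24 higher and 7 lower (15 and 7 adjusted over the list alone), and biogenesis regulators 9 of 20 higher and 4 lower. They had adjusted p = 0.00164 and 0.00490 by edgeR's fry and adjusted p = 0.615 and 0.816 with an estimated correlation. The transcription factor call was lost with library totals (adjusted p = 0.198 by edgeR's fry, in a range of 0.00187 to 0.198). The biogenesis call was lost without replicate 77 of day 0 (adjusted p = 0.0667 by edgeR's fry) or of day 2 (adjusted p = 0.0532), with library totals (adjusted p = 0.246) and with only the 2 days compared (adjusted p = 0.0576), in a range of 0.00438 to 0.246.

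Glucocorticoid targets had 12 of 19 higher and 6 lower (adjusted p = 0.0291 by edgeR's fry, adjusted p = 0.912 with an estimated correlation). It was lost without replicate 76 of day 0 (adjusted p = 0.0977 by edgeR's fry) or of day 2 (adjusted p = 0.179) and without replicate 77 of day 0 (adjusted p = 0.1996) or of day 2 (adjusted p = 0.143). It was also lost with RLE scaling (adjusted p = 0.0639 by edgeR's fry), library totals (adjusted p = 0.407), the replicate number as a block (adjusted p = 0.0553) and only the 2 days compared (adjusted p = 0.197), in a range of 0.00447 to 0.407. Prostaglandin pathway genes had 7 of 14 higher and 5 lower (adjusted p = 0.0379 by edgeR's fry, adjusted p = 0.918 with an estimated correlation), and their direction turned with library totals (adjusted p = 0.404). The call was also lost without replicate 76 of day 0 (adjusted p = 0.0870 by edgeR's fry) or of day 2 (adjusted p = 0.243) and without replicate 77 of day 0 (adjusted p = 0.2097), day 2 (adjusted p = 0.137) or day 6 (adjusted p = 0.0557). It was lost as well with RLE scaling (adjusted p = 0.0796 by edgeR's fry) and with only the 2 days compared (adjusted p = 0.153), in a range of 0.0294 to 0.404. Cytokine and chemokine genes had 10 of 15 lower and 1 higher (adjusted p = 0.00932 by edgeR's fry, adjusted p = 0.448 with an estimated correlation). This call was lost without replicate 77 of day 2 (adjusted p = 0.0533 by edgeR's fry, in a range of 0.00680 to 0.0533). Endothelial markers had 3 of 10 higher and 1 lower (3 and 0 adjusted over the list alone) and Schwann cell markers 2 of 6 higher and 1 lower. They had adjusted p = 0.01003 and 0.00102 by edgeR's fry and adjusted p = 0.878 and 0.631 with an estimated correlation. The Schwann call was lost without replicate 77 of day 2 (adjusted p = 0.0532 by edgeR's fry, in a range of 0.000391 to 0.0532). The endothelial call was lost without replicate 76 of day 2 (adjusted p = 0.0598 by edgeR's fry) or replicate 77 of day 2 (adjusted p = 0.0670). Other settings that ended it were library totals (adjusted p = 0.0672 by edgeR's fry), the replicate number as a block (adjusted p = 0.0539) and only the 2 days compared (adjusted p = 0.0562), in a range of 0.00968 to 0.0672.

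The other lists did not pass at day 6 against day 2, with adjusted p from 0.151 to 0.935 by edgeR's fry. They were anti-adipogenic regulators (5 higher and 7 lower of 22), progenitor markers (3 and 7 of 20), matrix genes (7 and 11 of 27, or 8 and 12 adjusted over the list alone), and UCP1-independent genes (3 and 3 of 7), and further acetyltransferase subunits (4 and 4 of 13), glycolysis genes (11 and 3 of 19), unfolded protein and stress genes (6 and 9 of 19) and skeletal muscle markers (1 and 0 of 5, summed level 11.6 CPM). The fry direction was upward for matrix, UCP1-independent and muscle lists while their median log2 changes were -0.26, -0.24 and -0.65, and downward for the anti-adipogenic and stress lists while their mean log2 changes were 0.03 and 0.07. Matrix and UCP1-independent genes turned to lower with library totals and with RLE scaling, and muscle markers with library totals, without passing (adjusted p from 0.0527 to 0.875 by edgeR's fry). Acetyltransferase subunits turned to lower and passed with library totals (adjusted p = 0.00729 by edgeR's fry). They turned without passing with only the 2 days compared (adjusted p = 0.426 by edgeR's fry) and without replicate 77 of day 0 (adjusted p = 0.567), in a range of 0.00729 to 0.936. Stress genes passed with RLE scaling (adjusted p = 0.0200 by edgeR's fry), library totals (adjusted p = 0.00761), only the 2 days compared (adjusted p = 0.0299) and without replicate 77 of day 0 (adjusted p = 0.0269), in a range of 0.00761 to 0.438. Anti-adipogenic regulators passed without replicate 77 of day 6 (adjusted p = 0.0320 by edgeR's fry, in a range of 0.0320 to 0.824) and turned to higher without replicate 76 of day 6 (adjusted p = 0.131). Of the lists with fewer than 3 tested members, mesothelial markers had 1 (highest count in a library 327), and lymphocyte, erythroid and epithelial markers had 0 (highest counts 8, 9 and 4).

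The order of the changes was followed through the calls of day 2 against day 0 and of day 6 against day 2. By these, 1710 genes rose in both steps, 959 rose by day 2 with no call after it, and 2184 rose by day 2 and fell after it. A further 1544 had no call by day 2 and rose after it, and 1049 had none and fell after it. Genes that fell by day 2 numbered 2266 that rose again, 1837 with no call after it and 748 that fell again, and 2162 genes had no call in either step. With library totals as the scaling, 948 genes rose and 1860 fell only in the later step, and 1368 fell and then rose. Genes that fell and then rose numbered 1455 without replicate 77 of day 0. Genes that fell in both steps numbered 466 without replicate 76 of day 2, 446 without replicate 77 of day 2 and 406 at a threshold of 0.01. Against the shared day 0 libraries, 3025 genes were higher at both later days and 3221 lower at both, and 1357 were called in opposite directions. In 20 simulations of unchanged groups against the same day 0 libraries these counts were 0, and independent lists of these sizes would share 1740, 1701 and 3441 genes. The log2 changes at the 2 later days had r = 0.63 (simulated 0.49) and covariance 1.54 (0.0298), over genes that are not independent replicates. With no gene changed, the simulations are no baseline for r or for what the shared controls may add to these overlaps. A split chosen after the data were seen set day 2 against 1 day 0 library and day 6 against the other. With replicate 76 of day 0 for day 2 and replicate 77 for day 6, 2817 genes were higher at both days, 2273 lower at both and 933 called in opposite directions, where independent lists would share 1554, 998 and 2521. The opposite assignment gave 2445, 2536 and 913 genes, where independent lists would share 1287, 1175 and 2459.7. The log2 changes correlated with r = 0.57 and 0.60, with covariances of 1.52 and 1.56. Each fit held 1 day 0 library, assumed to vary like the others.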

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

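Of the tests below, that of mitochondrial genes was set before its result was seen, though the rise of the mitochondrial share with the day was already known, and both tests of nuclear genes were set after it.

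HTSeq's summary lines, which enter no comparison, differed between days. It had set aside 6.43% ± 0.312 of all counted alignments as not unique at day 2 and 8.28% ± 1.10 at day 6, against 4.29% ± 0.186 at day 0 (SD, n = 2 libraries per day). The share outside any annotated feature was 3.19% ± 0.0608 at day 2, against 2.86% ± 0.0466 at day 0 and 2.70% ± 0.120 at day 6.

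The rise in not-unique alignments came to 3.98 points by day 6. Reads of nuclear genes with at most 90% of their 50-mers elsewhere would by their shares account for -13.6% of that rise. At day 2 they would account for 63.2% of 2.13 points. This decides nothing, as in replicates 76 and 77 of day 0 they would give 4.65% and 4.61%, above the 4.42% and 4.16% set aside. Mitochondrial genes with annotated nuclear copies may account for 1.23 points, or 30.8% of the rise at day 6, which left this source open. Of the 13 mitochondrial protein genes, 5 have over 90% of their 50-mers elsewhere and could not enter the sum, and a read can be counted at more than 1 alignment. For the 2674 nuclear genes with over 90% of their 50-mers elsewhere, 9 times the change of their counted share was -0.156 points. This decides nothing, as their lost reads cannot be counted. The days themselves, with their different transcripts, stay open and untested.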

How the results depend on the processing

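The settings below were fixed before the data were examined, but the basement membrane, clock and proteasome lists were chosen afterwards, and with them their values under each setting. Pseudocounts did not apply to counts and were not run, and the any-day result has no test beyond 2-fold. Of the values for gene lists, 943 kept their direction and their side of the threshold, 68 lost the call, 12 gained a call and 33 turned. For named genes these numbers were 1806, 33, 10 and 4, and for the lists added afterwards 266, 20, 7 and 4. Of the gene counts 137 stayed within 1.5 times their value and 11 did not, and of the time patterns 99 and 13. The replicate block changed no list or gene call other than those given beside their results. Where Ucp1 lost its only day 6 count, without replicate 76 of day 6, its log2 change at day 6 against day 0 was 0. Depth limits genes such as Ucp1 and Cidea, whose libraries hold 21 counts or fewer.

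The test for a change beyond 2-fold asks for more, so fewer genes passed: 2855 at day 2 against day 0 (1098 higher, 1757 lower), 3888 at day 6 against day 0 (2109 and 1779) and 2828 at day 6 against day 2 (1940 and 888). It ended the calls of Naa10, Prdm16, Letmd1, Cfd, Naa15 and Nat6 at day 2 against day 0, of Naa10, Dio2 and Prdm16 at day 6 against day 0, and of Pparg, Cebpa, Pde3b, Per1, Stat2 and Smtn at day 6 against day 2. A threshold of 0.01 ended the calls of Prdm16 at day 2 against day 0 and of Per1 and Smtn. With library totals, 3650 genes were higher and 6182 lower at day 6 against day 2, and 8 called genes turned direction and were called.

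With library totals the direction turned for these lists (adjusted p by edgeR's fry): inflammatory genes at day 2 against day 0 (0.894), basement membrane genes there (0.778), clock genes at day 6 against day 0 (0.00596), and at day 6 against day 2 matrix (0.257), UCP1-independent (0.0527), acetyltransferase (0.00729), prostaglandin (0.404), skeletal muscle (0.875) and proteasome genes (0.0166). The log2 changes of Prdm16, Per1 and Myh9 at day 6 against day 2 became -0.089, -0.051 and -0.013. At day 6 against day 2, matrix genes also turned with RLE scaling (0.814), no filter (0.992), the block (0.817) and only the 2 days (0.555). UCP1-independent genes turned with the same alternatives (0.295, 0.992, 0.0695 and 0.0655), acetyltransferase subunits with only the 2 days (0.426) and muscle markers with no filter (0.973). The cause of the lists' turns was not tested.

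Without 1 library at a time, 8140 to 10423 genes changed at day 2 against day 0, 8888 to 10295 at day 6 against day 0, 8115 to 9489 at day 6 against day 2 and 11373 to 12541 between any days. Some lists turned direction within these ranges of adjusted p by edgeR's fry. At day 2 against day 0 they were inflammatory genes (0.0840 to 0.870), macrophage markers (0.590 to 0.910) and basement membrane genes (0.317 to 0.708). At day 6 against day 0 they were prostaglandin genes (0.159 to 0.920) and interferon genes (0.310 to 0.979). At day 6 against day 2 they were anti-adipogenic regulators (0.0320 to 0.824), matrix genes (0.0873 to 0.975), UCP1-independent genes (0.0820 to 0.9999), acetyltransferase subunits (0.0751 to 0.811) and muscle markers (0.175 to 0.978). The log2 change of Flna there ranged from -0.32 to 0.11. The cause of these turns was not tested.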

Other observations

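The 9 lists in the next 2 paragraphs, and all tests in this part, were chosen after the data were seen.

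Ribosomal protein genes, whose products build the ribosome, rose slightly by day 2 and then fell. Of 77 tested, 57 were higher and 1 lower at day 2 against day 0 (median log2 change 0.34), 2 higher and 70 lower at day 6 against day 0 (-0.73), and 1 higher and 74 lower at day 6 against day 2 (-1.03). Their median share of 50-mers found elsewhere was 19.5%. Of 20 translation factors, 12 were higher and 1 lower, 6 higher and 10 lower, and 1 higher and 16 lower in the same order. Genes of branched-chain amino acid breakdown had 14 higher and 2 lower, 17 higher, and 17 higher of 17. Antigen presentation genes had 9 of 10 lower at day 2 against day 0, and 7 and 10 higher in the comparisons of day 6 with day 0 and with day 2. Adjusted p for these lists lay between 0.000527 and 0.0143 by edgeR's fry, and between 0.298 and 0.677 by limma's camera with an estimated correlation. At day 2 against day 0 the ribosomal, amino acid and antigen presentation calls were lost without replicate 76 of day 0 (adjusted p = 0.0553, 0.0553 and 0.0540 by edgeR's fry) or of day 2 (adjusted p = 0.0545 each), with lowest values of 0.00772, 0.00168 and 0.00772.

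Of 21 cholesterol synthesis genes, 14 were higher and 2 lower at day 2 against day 0, 16 and 1 at day 6 against day 0, and 13 and 2 at day 6 against day 2 (adjusted p = 0.0207, 0.00226 and 0.00319 by edgeR's fry, and 0.673, 0.597 and 0.449 with an estimated correlation). The call at day 2 was lost without replicate 76 of day 0 or day 2 and without replicate 77 of day 2. It was also lost without replicate 76 or 77 of day 6, a day not compared there, and with only the 2 days compared (adjusted p = 0.0633 by edgeR's fry). Of 31 proteasome genes, 29, 30 and 13 were higher in the 3 comparisons (adjusted p = 0.00181, 0.00139 and 0.0135 by edgeR's fry, and 0.564, 0.597 and 0.797 with an estimated correlation). At day 6 against day 2 they turned to lower with library totals (adjusted p = 0.0166 by edgeR's fry) and lost the call with RLE scaling (adjusted p = 0.0612), and only the 2 days compared (adjusted p = 0.2101). They also lost it without replicate 76 of day 0 or day 2 (adjusted p = 0.0521 and 0.0744 by edgeR's fry) and without replicate 77 of day 0 or day 2 (adjusted p = 0.218 and 0.0908). The range there was 0.00827 to 0.218. Of 14 clock genes, 3 were higher and 8 lower, 6 and 5, and 11 and 1 (adjusted p = 0.00181, 0.104 and 0.00101 by edgeR's fry, and 0.564, 0.892 and 0.298 with an estimated correlation). At day 6 against day 0 they turned to lower and passed with library totals (adjusted p = 0.00596 by edgeR's fry, in a range of 0.00596 to 0.446). Of 7 fibrillar collagen genes, 6 were lower and 1 higher at both days against day 0, and 3 lower and 2 higher at day 6 against day 2 (adjusted p = 0.00870, 0.00284 and 0.348 by edgeR's fry, and 0.564, 0.597 and 0.797 with an estimated correlation). Their call at day 2 was lost without replicate 76 of day 0 (adjusted p = 0.0538 by edgeR's fry) or of day 2 (adjusted p = 0.0545, with a lowest value of 0.00590). They passed at day 6 against day 2 without replicate 77 of day 6 (adjusted p = 0.0276 by edgeR's fry, with a highest value of 0.534). Of 15 basement membrane genes, 7 were higher and 7 lower, 6 and 8, and 4 and 6, and none of the 3 passed (adjusted p = 0.406, 0.0594 and 0.171 by edgeR's fry). At day 2 against day 0 their direction turned with library totals (adjusted p = 0.778 by edgeR's fry) and without replicate 77 of day 0 (adjusted p = 0.708), in a range of 0.131 to 0.778, while the median was 0.21 and fry pointed down. At day 6 against day 0 they passed with RLE scaling (adjusted p = 0.0326 by edgeR's fry), library totals (adjusted p = 0.0167), the replicate number as a block (adjusted p = 0.0436) and without replicate 77 of day 6 (adjusted p = 0.0222), in a range of 0.0167 to 0.176. From day 2 to day 6 they passed with library totals (adjusted p = 0.0166 by edgeR's fry) and without replicate 77 of day 6 (adjusted p = 0.0206), in a range of 0.0166 to 0.499. None of the 9 lists passed with an estimated correlation.

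Ucp1 was near 0 at day 6 while most other thermogenic genes were higher than at day 0. Loss of its reads to overlapping genes or to copies elsewhere was argued against, since both shares were 0%. Whether few cells became adipocytes stays open. General adipocyte genes summed to 69818 CPM at day 6, against 1077 at day 0, but the share of cells was not measured. The 3.44-fold lower median progenitor marker decided nothing. It replaced a first test, the 170.4-fold rise of the median general adipocyte gene, whose baseline near 0 does not bound that share. An end of cyclic AMP signalling with the switch from the IBMX-containing medium stays open, as it cannot be told apart from the day. Of the called cyclic AMP response genes, 57.1% fell from day 2 to day 6.

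Interferon response genes were lower at day 2 than at day 0 and higher again at day 6. The list's calls at day 2 against day 0 and at day 6 against day 2 were not repeated with an estimated correlation, by which no list passed. Both were also lost with the replicate number as a block (adjusted p = 0.0531 and 0.0539 by edgeR's fry). Both failed without replicate 76 or 77 of day 2, and the later one without 77 of day 6. Fewer macrophages at day 2 were argued against, since the median macrophage marker changed by -0.12 on the log2 scale (quartiles -0.26 and 0.29) and the median interferon gene by -3.31. From day 2 to day 6, 7 of 13 macrophage markers rose (median log2 1.41), so more macrophages at day 6 stay open. The scaling was argued against, since the interferon median nearest 0 over 3 scalings was -3.20. A fall of immune genes in general that ended with the induction medium was argued against by the cytokine and chemokine genes, of which 9.09% of those called rose from day 2 to day 6. Antigen presentation genes did follow the pattern, with 9 of 10 lower at day 2 against day 0 and 10 of 10 higher at day 6 against day 2, so a fall shared by part of the immune genes stays open. Components of the media change with the day and stay open, as does a biological effect of the day itself, both untested.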
